A study of Mus musculus with 32 samples.

How the data were processed

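RNA abundance was measured in mouse prefrontal cortex on 32 membrane arrays of spotted complementary DNA clones. Per the labels, the animals came from lines bred for severe (Withdrawal Seizure-Prone, WSP) or mild (Withdrawal Seizure-Resistant, WSR) ethanol withdrawal, with 2 independently selected replicates of each line. Mice of both sexes breathed ethanol vapor for 72 h or air, and tissue was taken at 0 h of withdrawal. Each array was probed with radioactively labelled complementary DNA from 2 pooled animals, with 2.5 µg of RNA from each. Animals given ethanol received a priming dose of 1.5 g/kg (1.75 g/kg in the second WSP replicate), and animals of both treatments received 68.1 mg/kg of the alcohol dehydrogenase inhibitor pyrazole.

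The deposited array files give spot signal intensity on a linear scale without background subtraction, together with 1 background intensity per array, per the file headers. The scanner, the image software and the date of each array are not given in the sources used here. The authors' value table holds a score per spot, scaled within each array. From the values, that score is 8 plus 2 times the z-score of the log signal, to within 6.58e-09, and it is blank where the signal did not exceed the background of the array (99.976% of cells). The table has between 827 and 4451 values per array. The array files were used for the comparisons and the value table as an alternative.

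Each array had 5355 spots, of which 192 were control spots and 5163 carried clones. A feature was named from its deposited title where the title names a gene, or from the 1 mouse symbol whose synonyms include the clone's sequence accession. This gave 1432 named features with 1411 distinct names. Of the features, 1117 were named by title and 289 by the synonym alone. A further 21 and 5 took the symbol of a gene list, by a similar protein and by synonym as given below. The other 3731 features had no gene name and were tested but are not named. For the gene lists, 159 features were matched to a current symbol, 133 by title, 21 by a title that gives a highly similar protein and 5 by synonym. Chromosomal positions of the clones are not given in the sources used here.

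Signals were corrected with the normexp method with an offset of 50, control spots were dropped, and log2 signals were quantile normalised between arrays (limma 3.58.1, R 4.3.3). A linear model with 1 mean per sex, line and treatment was fitted in limma to 31 arrays. The array of female WSR ethanol replicate 2-1, which the labels mark as excluded, was left out. The file of female WSP ethanol replicate 1-2 carries in its header the name of replicate 1-1 of the same group, while its values differ from that array's, so its pool number rests on the labels. Tests were limma's moderated, two-sided tests, adjusted by Benjamini and Hochberg over the 5163 features within each of 9 comparisons, with a threshold of 0.05. The selection replicates were collapsed, as the series record describes, and both replicates' differences were compared in sign. Signal over background stands in for depth: 460 features exceeded the background on every array and 1 on none, and the number of arrays limits the precision. Where all arrays of a group lay at or under the background, a fold against that group is a lower bound taken from the background, and none is given where it cannot be had. The log2 differences printed for such features are the fitted ones.

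Replicate numbers (selection replicate and pool) were checked for pairing of air and ethanol arrays. The correlations of the deviations of same-numbered arrays from their group means lay between -0.131 and 0.241, with values at or below 0.01 in every sex and line, so the numbers were not used as pairs. A block on them was run as an alternative.

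Features were chosen for naming by a rule set before the data were examined. Where at least 10 named features passed with the same sign in both selection replicates, the 12 largest positive and 12 largest negative differences were taken. Elsewhere the 5 positive and 5 negative named features with the smallest unadjusted p were taken and are given as not passing where they do not. Within each list, the 3 genes with the smallest unadjusted p in the averaged ethanol comparison were taken. Some of the features chosen in these ways are not given.

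Before the data were examined, 27 gene lists of pathways, complexes, cell types and sex-linked genes were fixed. With at least 5 measured genes, 20 could be tested. They were activity-regulated early genes, glucocorticoid-responsive genes, stress chaperones, ethanol metabolism and oxidative defence, cholesterol and fatty acid synthesis, inflammatory and interferon genes, apoptosis, glutamate synapse, synaptic vesicle release, voltage-gated ion channels, chromatin modifiers, oxidative phosphorylation, ribosomal proteins, proteasome subunits, and markers of neurons, astrocytes, oligodendrocytes, microglia, endothelial and mural cells, and blood. The lists for GABA receptors, interneurons, oligodendrocyte precursors, meningeal and choroid plexus cells, striatal neurons, olfactory bulb and sex-linked genes held too few. Lists were tested with camera against all other features, named or unnamed, with a preset correlation of 0.01 between genes and with an estimated one. The brightest feature per gene name was used.

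The fit was tested on simulated arrays with the feature means and the array scatter of the real ones, in which 200 features were shifted in the ethanol arrays of 1 group or of all groups. Shifts were added on the normalised log2 scale. The scatter had 1 SD per array and was independent between features, without the blocks of the membrane. The share recovered is given beside each single and averaged ethanol comparison. The contrasts between sexes, between lines and of interaction were not simulated. In the same kind of data, camera called the 1 list that had been moved and 0 others. That list was larger than the real ones, which held between 5 and 14 measured genes. The result therefore does not show what camera could find in them.

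Alternatives fixed before the data were examined were no background correction, median scaling, cyclic loess, the authors' value table, leaving out the dimmest features at a milder and a stricter limit on mean signal, keeping the excluded array, fitting only the groups compared, selection replicate as a block, selection replicate and pool number as a block, a trended robust prior, array weights, and leaving out each array in turn. Alternatives chosen after seeing the data were a common median before normexp, centring each array's deviations by block of spots or by row within blocks, row centring with array weights, the range of the arrays as a block, fits to arrays of 1 range, and fits of each sex alone. For every model, 100 random regroupings of the arrays, or all 35 where there are fewer, were fitted in the same way. Effects of the 4 ethanol comparisons were correlated across features and compared with 100 reassignments of treatment within groups.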

Results

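RNA from the prefrontal cortex of WSP and WSR mice, lines bred for severe and for mild ethanol withdrawal, was measured on 32 membrane arrays. They form 8 groups of 4 arrays by sex, line and treatment, and each array stands for a pool of 2 animals. In each group, 2 arrays came from each independently selected replicate of the line, numbered 1 and 2 before the pool number, as in replicate 2-1. The labels mark female WSR ethanol replicate 2-1 as excluded, so that group had 3 arrays in the comparisons.

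The arrays differed in the range of their signal. On 20 of them the 95th percentile of spot signal was between 13.2 and 35.8 times the median, and on 12 it was between 2.73 and 8.47 times. All 16 male arrays and the arrays of pool 2 of female WSP had the wide range, while those of pool 1 of female WSP and all female WSR arrays had the narrow one. The median signal was between 8.79 and 76.6 on wide-range arrays and between 87.8 and 609 on narrow-range ones. The share of features above background had a median of 58.3% (40.9% to 82.5%) on wide-range and 27.6% (15.8% to 49.3%) on narrow-range arrays. Deviations from the group mean had an SD of 0.196 and 0.383 on the log2 scale, in the same order. Sex and range therefore coincide in WSR, and partly in WSP, while air and ethanol arrays of each sex and line have the same mix of ranges.

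**Figure D1:**
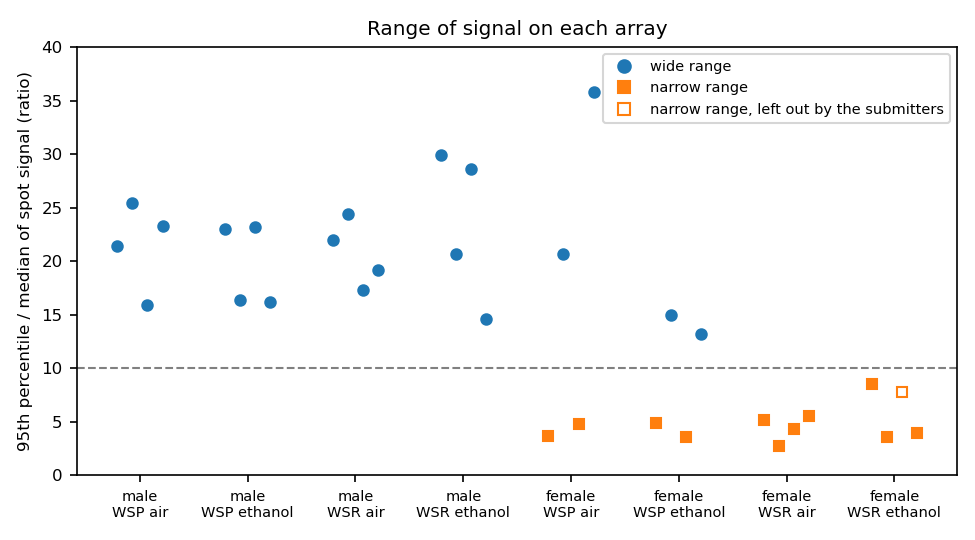
The 95th percentile of spot signal divided by the median (vertical axis, ratio) for each of the 32 arrays, by group; circles are wide-range arrays, squares narrow-range arrays and the open square is the array the submitters left out. The gap between 8.47 and 13.2 holds no array, and the dashed line marks a ratio of 10.

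The first question was which transcripts differ after 72 h of ethanol vapor within each sex and line, as the series record frames it. In male WSP mice, the highest differences at the smallest unadjusted p were for pale ear, a gene of pigment granule formation (log2 difference 0.53 ± 0.19, SE, with 4 arrays in each group), and for Atp8b1, a phospholipid flippase (0.41 ± 0.16). The transcription cofactor Trim24 (0.37), the immunoglobulin light chain Igkc (0.34) and the nuclear membrane protein gene Nrm followed, the last above background on 1 ethanol array and 0 air arrays. Pale ear exceeded the background on 4 ethanol and 0 air arrays. With rows of spots centred, Atp8b1 stood at 0.27. Lower values were seen for intersectin, an endocytic scaffold (-0.47 ± 0.20), for the chromatin remodelling subunit BAF53a (-0.43), outer arm dynein light chain 4 (-0.39), the farnesyltransferase alpha subunit (-0.28, or -0.19 with rows of spots centred) and Ndrg2, a gene of astrocytes (-0.44 ± 0.22). None of these passed limma's test (adjusted p = 1.00). Across all features 0 were called and 45 had an unadjusted p under 0.05, where chance alone gives 258. In simulated data this fit recovered 0% of shifts of 0.5 and 100% of shifts of 1 on the log2 scale, while fits with array weights and with only the compared groups recovered 67.0% and 63.5% of shifts of 0.5 and also called 0 features in the real data (189 and 173 at an unadjusted p under 0.05).

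In male WSR mice, mitochondrial carrier homolog 1 (0.60 ± 0.19) and the cell adhesion molecule nectin-3 alpha (0.74 ± 0.25) had the leading positive differences. They were followed by the synaptic adhesion gene Lrfn5 (0.51), the aryl-hydrocarbon receptor-interacting protein (0.41), and the RNA exosome subunit gene Exosc1, which exceeded the background on 2 ethanol and 0 air arrays. The transcription factor Stat6 stood at -0.43 ± 0.19, the translation termination factor G1 to phase transition 1 at -0.40, and the iron storage subunit ferritin light chain 1 at -0.31. With rows of spots centred, mitochondrial carrier homolog 1 stood at 0.34, Lrfn5 at 0.31, the aryl-hydrocarbon receptor-interacting protein at 0.15 and Stat6 at -0.24. The cystine transporter Slc7a11 exceeded the background on 1 air and 0 ethanol arrays. None passed (adjusted p = 1.00), limma called 0 features, and 39 had an unadjusted p under 0.05. The simulated recovery was 0% at 0.5 and 98.5% at 1, and at 0.5 it was 72.0% with array weights and 70.5% with only the compared groups, which also called 0 in the real data (210 and 166 at an unadjusted p under 0.05).

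In female WSP mice, the leptin receptor, which senses the adipose hormone leptin, had the smallest adjusted p, with a difference of 0.66 ± 0.15 (adjusted p = 0.701, with 4 arrays in each group). Next came the peptidase tripeptidyl peptidase II (0.64 ± 0.16), the peptide hormone guanylate cyclase activator 2 (0.62), Plekha5 (0.53) and the zinc finger protein 57 (0.52). The leptin receptor, tripeptidyl peptidase II and Plekha5 exceeded the background on 3 ethanol and 0 air arrays each. On the lower side stood tubulointerstitial nephritis antigen (-0.54 ± 0.17, but -0.07 with the wide-range arrays alone), gene trap locus-13 (-0.55, but 0.15 with the wide-range arrays alone and 0.05 with array weights), the sodium pump subunit Na+/K+ ATPase beta 1 (-0.53, with -0.06 at its other feature), Ndrg2 (-0.53, but 0.15 with the wide-range arrays alone) and the neurogenic transcription factor achaete scute homolog 1 (-0.41). No feature passed, with 0 called by limma and 173 at an unadjusted p under 0.05, while the simulated recovery was 10.5% at 0.5 and 94.0% at 1. With array weights 6 features were called, among them Plekha5, the leptin receptor, the interferon-induced Mx2 and the amino acid catabolic enzyme BCKDH E1 beta, and with the wide-range arrays alone 5 unnamed ones, while array weights with rows of spots centred gave 0 (444 at an unadjusted p under 0.05). With rows centred the leptin receptor stood at 0.34, tripeptidyl peptidase II at 0.28, guanylate cyclase activator 2 at 0.31 and the zinc finger protein 57 at 0.21.

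In female WSR mice, limma called 5 features, all lower after ethanol, by -1.27 to -1.79 on the log2 scale (smallest adjusted p = 0.00418, with 3 ethanol and 4 air arrays). None of the 5 has a gene name, and 4 of them lie in 1 block of the membrane that holds 322 features. Among named features, the small GTPase RhoC had the smallest adjusted p among positive differences (0.97 ± 0.22, adjusted p = 0.0666), followed by src-like adapter protein (1.22 ± 0.34) and the ubiquitin ligase subunit Rbx1 (0.62). Cbfa2t3 and Nsl1 did not exceed the background in either group. On the lower side, Clstn2, a postsynaptic membrane protein (-1.17 ± 0.28), C2cd2 (-1.18) and the arrestin-related Arrdc3 (-0.90) shared an adjusted p of 0.0884, and the last 2 exceeded the background on 0 ethanol arrays. The creatine synthesis enzyme guanidinoacetate methyltransferase stood at -0.94, or -0.60 without female WSR air replicate 2-1, and Vxn exceeded the background on 1 air and 0 ethanol arrays. With rows of spots centred, Arrdc3 stood at -0.53 and Rbx1 at 0.40. At an unadjusted p under 0.05 there were 784 features, where chance gives 258. The simulated recovery was 33.0% at 0.5 and 83.5% at 1, with 188 and 207 false calls. With the spread of the compared groups alone, with array weights and with selection replicate and pool number as a replicate block, limma called 0, and with cyclic loess it called 959, of which 578 were higher and 381 lower.

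Averaged over the 4 groups (15 ethanol and 16 air arrays), RhoC (0.31 ± 0.10), the enzyme BCKDH E1 beta (0.33 ± 0.11) and Mx2 (0.31 ± 0.11) led the positive differences, before the zinc finger protein 57 and the axon guidance ligand ephrin A2 (both 0.22). Protein phosphatase 1B beta (-0.27 ± 0.08), Ndrg2 (-0.36 ± 0.11, or -0.23 with rows of spots centred), the solute carrier gene Slc35e4 (-0.30), nuclear transcription factor-Y beta (-0.28) and the C-type lectin-like receptor 2 (-0.22) led the negative ones. BCKDH E1 beta and the zinc finger protein 57 were above their air values in all 4 groups, and protein phosphatase 1B beta, Slc35e4, nuclear transcription factor-Y beta and the C-type lectin-like receptor 2 were below theirs. All 10 had an adjusted p of 0.891, and limma called 0 features. There were 204 at an unadjusted p under 0.05, while the simulated recovery was 93.0% at 0.5 and 100% at 1. Simulated scatter was independent between features, while the blocks of spots held 32.3% of the variance of the real averaged differences. The reach of the test in the real data is therefore not known.

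**Figure D2:**
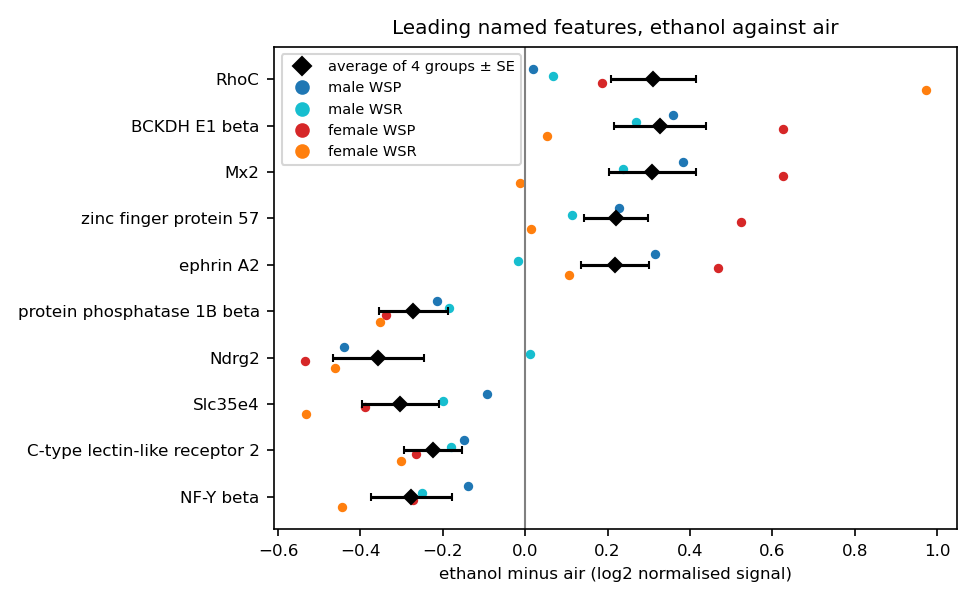
Ethanol minus air on the log2 scale (horizontal axis) for the 10 named features that lead the averaged comparison; diamonds with bars are the average of the 4 groups ± SE and circles the single groups. None of the 10 passed the test (adjusted p = 0.891).

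Of the gene groups fixed beforehand, camera called 0 of 20 in the averaged comparison, and the smallest adjusted p was 0.392 (0.571 with an estimated correlation). Among 12 measured activity-regulated early genes, 3 were higher and 9 lower after ethanol (adjusted p = 0.392), with the immediate early transcription factor Egr1 at -0.32 ± 0.18, the synaptic scaffold Homer1 at -0.19 and Fosl2 at -0.14. Of 14 genes of oxidative phosphorylation, 3 were higher and 11 lower (adjusted p = 0.392), led by the respiratory chain subunits Uqcr11 (-0.29 ± 0.16), Cox6a1 (-0.16) and Ndufa9 (-0.18). Among 12 ribosomal proteins, 5 were higher and 7 lower (adjusted p = 0.392), with Rpl19 at -0.31 ± 0.12, Rpl30 at -0.22 and Rpl36 at 0.14. Of 8 voltage-gated ion channels, 5 were higher (adjusted p = 0.438), led by the calcium channel subunits Cacna2d1 (0.16), Cacna1a (0.20) and Cacnb4 (0.29 ± 0.20). Proteasome subunits had 7 of 9 higher (adjusted p = 0.475), with Psmb9 at 0.21, Psmb5 at 0.10 and Psmd4 at 0.19.

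The other pathways did not pass either. Among genes of ethanol metabolism and oxidative defence, 3 of 8 were higher (adjusted p = 0.991), with the ethanol-oxidising Cyp2e1 at 0.28 ± 0.11, Gsr at -0.16 and Prdx4 at -0.05. For the adjusted p of 0.800, the glucocorticoid-responsive genes had 3 of 5 higher (Tsc22d3 -0.22 ± 0.09, Tgm2 0.17, Glul -0.07) and cholesterol and fatty acid synthesis 1 of 5 (Fdps 0.13, Insig1 -0.08). At the same adjusted p, the glutamate synapse had 3 of 5 higher (Dlg3 0.17, Grin1 0.24, Homer1 -0.19), vesicle release 2 of 6 (Sypl1 0.22, Stx7 -0.08, Syt4 -0.14) and chromatin modifiers 6 of 11 (Sirt1 0.10, and 0.10 at its other feature, Ezh2 0.09, Kmt2a 0.07). Inflammatory and interferon genes had 6 of 11 higher (adjusted p = 0.83), with Rela at -0.19 and Nfkb1 at -0.18. Stress chaperones had 1 of 6 higher (Hspb8 0.21, Hspa4 -0.10, Hspe1 -0.05) and apoptosis genes 3 of 6 (Casp6 -0.08, Mdm2 0.06, Dapk3 -0.04), both at an adjusted p of 0.907. The median or the mean of the list had the opposite sign to camera's direction for the glucocorticoid, ethanol metabolism, inflammatory and apoptosis lists. The only measured gene of the GABA list, the receptor subunit Gabbr1, stood at -0.38 ± 0.16.

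Markers of cell types did not pass either. Of 8 astrocyte markers 3 were higher (adjusted p = 0.438), and Ndrg2 was the 1 gene below 0.05 when adjusted over the list alone, against 0 over all features. Fgfr3 stood at -0.15 and Vim at -0.24. All 5 endothelial and mural markers were higher (adjusted p = 0.392), with Ramp2 at 0.26 ± 0.10 and 0.07 at its other feature, Klf2 at 0.10 and Kcnj8 at 0.12. At an adjusted p of 0.800, neuron markers had 2 of 5 higher (Thy1 -0.11, Chn1 -0.15, Syn1 0.09), oligodendrocyte markers 2 of 5 (Nkx6-2 0.14, Qdpr -0.19) and microglia markers 1 of 5 (Ctsb -0.04, Fcer1g 0.05). Blood markers had 5 of 7 higher at that adjusted p (Hbb-b2 0.28 ± 0.13, H2-Aa -0.22, Hba-a1 -0.06 at its brightest feature, which the count uses, and 0.11 at its other feature). In lists too small to test, the interneuron peptide gene Sst stood at -0.25 ± 0.09, Dlx5 at 0.08 and Slc32a1 at -0.02, the precursor marker Ccnd1 at 0.24, and the choroid plexus and meningeal genes Igf2 at 0.05, Ttr at 0.06 and Folr1 at -0.02. Striatal and olfactory bulb markers were not measured. In the 4 single ethanol comparisons camera also called 0 lists, with smallest adjusted p of 0.647 in male WSP, 0.109 in male WSR, 0.774 in female WSP and 0.333 in female WSR.

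Whether the response to ethanol differs between the sexes was tested by interaction. Tripeptidyl peptidase II (difference of log2 differences 0.48 ± 0.17, females minus males), RhoC (0.54 ± 0.21), hnRNP A1 (0.41), hepatic lipase (0.38) and the transcription factor Spi-C (0.35) had the leading positive values. Vxn (-0.62 ± 0.20), tubulointerstitial nephritis antigen (-0.52), achaete scute homolog 1 (-0.44), the Ubc7p homolog (-0.61) and COP9 subunit 7b (-0.73) had the leading negative ones, of which Vxn, the Ubc7p homolog and COP9 subunit 7b stood at -0.39, -0.24 and -0.45 with rows of spots centred. None passed (adjusted p = 0.965). Limma called 0 features, 161 had an unadjusted p under 0.05, and camera called 0 lists (smallest adjusted p = 0.269, for the proteasome and oligodendrocyte lists).

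Whether the lines bred for severe and mild withdrawal respond differently was tested in the same way, as WSP minus WSR. The leptin receptor (0.51 ± 0.15), N4bp2l1 (0.51), the membrane-remodelling gene Chmp7 (0.41), the tissue inhibitor of metalloproteinase 3 (0.45) and Clstn2 (0.71 ± 0.26) led the positive values. The ATP-gated channel P2X1 (-0.53 ± 0.17), Stox2 (-0.45), the neuroblastoma ras oncogene (-0.50), Nsl1 (-0.39) and the transcription factor gene hairy/enhancer of split 6 (-0.62) led the negative ones. With rows of spots centred, the leptin receptor stood at 0.15, N4bp2l1 at 0.31, the tissue inhibitor at 0.22, Stox2 at -0.27 and Nsl1 at -0.20. None passed (adjusted p = 0.944), and limma called 0 features, with 254 at an unadjusted p under 0.05. Camera called 0 lists (smallest adjusted p = 0.651). With cyclic loess 10 features were called, all negative.

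Across the 5163 features, the ethanol differences of the 4 groups had a mean pairwise Pearson r of 0.04 (permutation p = 0.366 from 100 reassignments, which ranged from -0.08 to 0.15). The 6 pairs ranged from -0.03 for male WSP with male WSR to 0.12 for female WSP with female WSR, each with an adjusted permutation p of 1. Features are not independent replicates, so r describes likeness only.

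Females and males in air, 8 arrays each, differed in 527 features, of which 122 were higher and 405 lower in females. Of the named ones, 27 were higher and 78 lower, all with the same sign in both selection replicates. The replicates are the same arrays that gave the calls, and both have the same mix of ranges. The shared sign is therefore not independent support. Higher in females were Clstn2 (log2 difference 1.01 ± 0.18, adjusted p = 7.16e-04), the PPARgamma cofactor Pgc2 (0.90 ± 0.27), the lipid hydrolase Abhd4 (0.82), the centrosome gene Nedd1 (0.82) and the endocytic adapter Sh3kbp1 (0.81). None of these 5 exceeded the background on any male array in air, so the folds are lower bounds, of at least 1.60 for Clstn2 and 1.44 for Sh3kbp1. Also higher were 1600014C10Rik (0.78), Arrdc3 (0.76 ± 0.15), guanidinoacetate methyltransferase (0.59), the splicing factor gene U2af1l4 (0.58), the NADPH-forming isocitrate dehydrogenase 1 (0.55) and the zinc finger factor MAZR (0.55, at least 1.23-fold). Without female WSR air replicate 2-2, Pgc2 stood at 0.57, Abhd4 at 0.54 and Nedd1 at 0.44. The spots of Pgc2, Abhd4 and Nedd1 lie close together in the same block, at rows 8 to 11 and columns 24 to 25. Clstn2, Sh3kbp1, Arrdc3, guanidinoacetate methyltransferase, U2af1l4 and MAZR lie in another block, all within columns 1 to 7. With rows of spots centred, Abhd4, Nedd1, guanidinoacetate methyltransferase, U2af1l4, isocitrate dehydrogenase 1 and MAZR did not pass (adjusted p of 0.0563 to 0.138). Sh3kbp1 passed there, at 0.45.

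Lower in females were the DNA replication gene origin of replication 3 homolog (-1.06 ± 0.17, adjusted p = 2.40e-04), RP42 (-0.95 ± 0.12, adjusted p = 3.62e-05) and Dio2, which activates thyroid hormone (-0.88 ± 0.18). The G protein alpha 11 subunit (-0.87 ± 0.13), RhoC (-0.83 ± 0.14), DNA topoisomerase III beta (-0.83, or -0.54 with rows of spots centred), the Golgi SNARE GS15 (-0.82) and the stress transcription factor Ddit3 (-0.80) followed. Lrrc49 and the Rac activator Dock5 (both -0.77), the DNA damage kinase Atr (-0.76) and Uggt1, which checks protein folding in the endoplasmic reticulum (-0.76), completed the set. Some members of the fixed lists passed and were chosen here because they passed. The respiratory chain subunits Ndufs4 (-0.56 ± 0.12) and Cox8a (-0.45 ± 0.11) were lower in females. So were Mbd2, which binds methylated DNA (-0.62 ± 0.15), and Enpp2, which makes lysophosphatidic acid (-0.48 ± 0.12). Also lower were Ier2 (-0.42), Mcl1 (-0.40), Dlg4 (-0.32), Rpl15 (-0.32) and Fjx1 (-0.37). Qdpr, which recycles the cofactor tetrahydrobiopterin, was higher (0.43 ± 0.13). Adjusted over the list alone, 3 of 14 genes of oxidative phosphorylation and 3 of 6 stress chaperones passed, against 2 and 1 over all features. As groups, 0 of 20 lists were called by camera (smallest adjusted p = 0.513, and 0.630 with an estimated correlation).

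**Figure D3:**
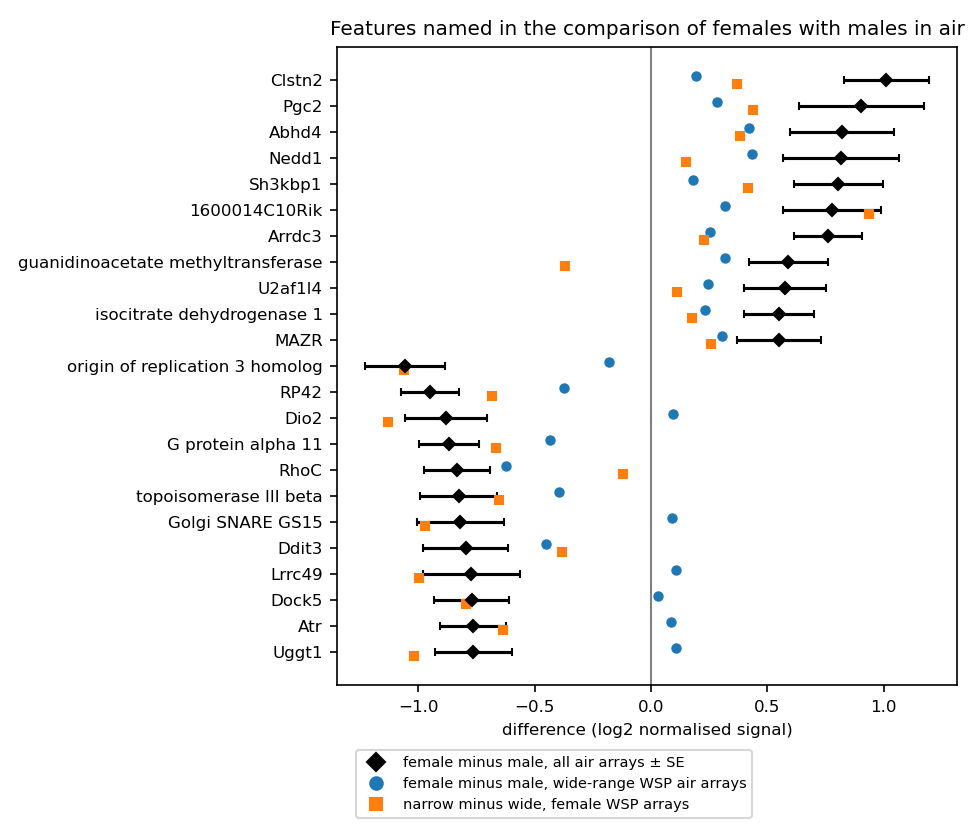
Differences on the log2 scale (horizontal axis) for features named in the comparison of the sexes in air; diamonds with bars are females minus males over 16 arrays ± SE, circles the same difference within the wide-range WSP air arrays, and squares narrow-range minus wide-range arrays of female WSP. Dio2 stands at -0.88, at 0.09 within the wide-range arrays and at -1.13 between ranges, while RhoC stands at -0.83, -0.62 and -0.12.

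The range of the arrays differs between the sexes, and within the wide-range arrays alone the WSP air samples (2 female and 4 male arrays) gave 1 call. With both treatments (4 female and 8 male wide-range arrays, treatment as a covariate), 84 features were called, of which 33 were among the 527, all in the same direction. The air arrays of that fit also took part in the calls of the 527, so the shared direction is not independent support. With the range as a block, whose term is estimated within female WSP and applied to female WSR too, limma called 0 features (smallest adjusted p = 0.400, with 394 at an unadjusted p under 0.05). The signed median over the 527 was then 0.28 in place of 0.57, and the median SE 0.18 in place of 0.14. In that fit Uggt1 (-0.00 ± 0.14), Lrrc49 (-0.03 ± 0.24), Dio2 (-0.03 ± 0.14), 1600014C10Rik (0.07 ± 0.25), GS15 (-0.09 ± 0.20) and Dock5 (-0.18 ± 0.18) had no difference beyond their SE. RhoC stood at -0.74 ± 0.21, Clstn2 at 0.74 ± 0.26 and RP42 at -0.44 ± 0.12, and none of them passed. Within the wide-range WSP air arrays alone, RhoC stood at -0.62, Clstn2 at 0.19 and RP42 at -0.37. In WSR air, where sex and range coincide, they stood at -1.01, 1.57 and -1.18. The WSR air arrays alone, 4 of each sex, gave 374 calls, 26 higher and 348 lower in females. Of these, 298 were among the 527, to whose calls the same arrays contributed. Over the 527, the signed median was 0.78 in WSR air and 0.11 in wide-range WSP air. The 527 thus rest mostly on the line in which sex and range cannot be told apart. Unlike the range block, selection replicate and pool number as a replicate block gave 712 calls, median scaling 153 and cyclic loess 57 (35 higher and 22 lower). The sex-linked genes did not check the labels: the Y-linked Eif2s3y differed by -0.14 ± 0.11 (adjusted p = 0.489), and Kdm6a, which escapes X inactivation, did not exceed the background on any array in air. Over both treatments, Eif2s3y exceeded the background on 14 of 16 male, 4 of 4 wide-range female and 2 of 11 narrow-range female arrays.

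WSP and WSR mice in air, 8 arrays each, differed in 9 features, 5 higher and 4 lower in WSP (smallest adjusted p = 0.0284). The 8 arrays of each kind came from 2 selection replicates, so limma's p does not measure variation between separately selected lines. The named features among the 9 were 2310011J03Rik (0.43 ± 0.09) and the sodium/proton exchanger Slc9a7 (0.57 ± 0.12), both at an adjusted p of 0.0490 and both higher in the 2 selection replicates. These replicates are the same arrays that gave the calls, so the shared sign is not independent support. The calls of 2310011J03Rik and Slc9a7 were lost in 19 and 18 of 32 alternatives, and the count of 9 was 0 without any 1 of 6 single arrays. The others, without a gene name, were 3 higher features at 0.58 to 0.81 and 4 lower ones at -0.80 to -1.12. Of the 9 features, 4 lie in the block of spots that holds Clstn2. That block was raised on female WSR air replicate 2-1 (median deviation 1.09). Not passing were Bclaf1 (0.66 ± 0.17, adjusted p = 0.104), Ankrd28 (0.35) and Akr1cl (0.36) on the higher side, and Arrdc3 (-0.59 ± 0.15), Clstn2 (-0.70), guanidinoacetate methyltransferase (-0.52), the zinc finger protein 46 (-0.38) and Ufl1 (-0.38) on the lower side. At an unadjusted p under 0.05 there were 471 features, and camera called 0 lists (smallest adjusted p = 0.200). The count was 0 with the range as a block, 1 with selection replicate as a block, 44 with selection replicate and pool number as a replicate block, and 152 with array weights. It was 0 among male arrays alone and 0 among narrow-range female arrays alone, with 327 and 256 features at an unadjusted p under 0.05. With rows of spots centred, limma called Bclaf1 (0.66, adjusted p = 0.0186) and Ufl1 (-0.36, adjusted p = 0.0404) but not Slc9a7 (0.44, adjusted p = 0.0740). Ankrd28 and Akr1cl both stood at 0.21 in that fit.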

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

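The tests of membrane position, of the shared spread, of the raised block and of likeness between the 4 groups were chosen after the results they concern had been seen, and the others before.

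The 527 features that differed between the sexes in air were more than regrouping the arrays gave: 1 of 100 groupings, the real one, gave as many and the highest of the others gave 82. This excludes chance only for regroupings that ignore range and selection replicate. In WSR the real grouping is also the split of wide-range from narrow-range arrays. A shift of whole rows or blocks of spots is argued against as the whole cause. With rows of spots centred 428 features were called, 289 of them among the 527 and with the same sign. Centring takes out the median of each row, so a patch or gradient within a row would remain. Position on the membrane at that finer scale stays open. For the range of the arrays, narrow minus wide within the female WSP ethanol arrays, signed by the sex difference, had a median of 0.26 over the 527 (quartiles 0.04 and 0.49) against 0.57 for the sex difference, with 409 in the same direction. For the sex of the animals, females minus males among the wide-range WSP ethanol arrays had a signed median of 0.16 (quartiles -0.02 and 0.34), with 382 in the same direction, and in the wide-range air arrays, which took part in the calls and were not the arrays of the test, it was 0.11 (quartiles -0.05 and 0.27). The medians in ethanol arrays lie between the limits set beforehand for a whole cause and for none, while that in air lies under them, so range and sex may each account for a part, but for the 527 as a set they cannot be told apart because in WSR every female array has the narrow range and every male one the wide range.

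The 5 features called after ethanol in female WSR were matched or exceeded in 26 of 35 splits of the 7 arrays, the highest with 211, so chance cannot be excluded, and splits that call far more point to a structure of the arrays (a split by pool gave 210). Under cyclic loess the real split gave 959, 10 of 35 gave as many and the highest gave 1445. One spread shared by arrays of unequal scatter (SD 0.196 and 0.383 on wide-range and narrow-range arrays) is a candidate cause: with the spread of the compared groups alone the log2 differences are the same by construction, between -1.27 and -1.79, and the count is 0. That fit recovered 0.5% of simulated shifts of 0.5, 41.0% of shifts of 1 and 100% of shifts of 2. A raised block of spots on female WSR air replicate 2-1 (median deviation 1.09, against -0.36 to 0.32 on the other arrays) is argued against as the whole cause, since 4 of the 5 features were still called without that array. The median size of the 5 differences was then 1.19 in place of 1.65, so the array may account for a part. Leaving it out does not test a patch of spots on the other arrays, so position stays open. A response to ethanol stays open. The effects of the 2 selection replicates had an r of 0.00128 across features (9 of 18 arrangements as high, exact one-sided p = 0.5, highest 0.299). With 18 arrangements this p could not fall under 0.05, so the test could not have shown a response.

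In the averaged ethanol comparison, the 16 blocks of spots held 32.3% of the variance of the log2 differences, against at most 0.565% in 100 shuffles, and 4 of the 5 leading positive features lie in 1 block. With rows of spots centred, the median size of the 10 leading differences was 0.23 in place of 0.29, but the 10 were picked for their small p, so position stays open as a cause. Over the 9 comparisons the leading features kept between 62.5% (line interaction) and 90.1% (WSP against WSR in air) of their median size. A response to ethanol shared by the 4 groups stays open, because the mean r between their effects was 0.0366, within the range of the reassignments (highest 0.151). As 0 features were called, all 100 of 100 regroupings gave as many, and the highest of the others gave 113.

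For the other comparisons, the splits gave these values. In male WSP and male WSR all 35 splits gave the real count of 0, and the highest other was 0. In female WSP all 35 reached the real count of 0, and the highest other, 254, came from the split of wide-range from narrow-range arrays, which is also the split by pool. For the interactions with sex and with line, 100 of 100 reached the real count of 0, with highest others of 55 and 29, and for the gene lists 100 of 100 with a highest other of 3. For the 9 features that differed between WSP and WSR in air, 3 of 100 regroupings gave as many, the highest other with 14, which excludes chance only for regroupings that ignore range and selection replicate. The range differs between the lines in females, and limma called 0 with the range as a block (366 at an unadjusted p under 0.05), 1 with selection replicate as a block and 0 among males alone (327 at an unadjusted p under 0.05).

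Single arrays stood far from the others of their group in 11 of 125 values tested in the air groups (3 measures per array and the named features that passed), where chance gives about 6.25. The median signal was 609 on female WSR air replicate 1-2, against 344 to 355 on the others. On the log2 scale of normalised signal, female WSR air replicate 2-2 stood apart for Pgc2 (9.13, others 6.51 to 6.88), Abhd4 (8.40, others 6.22 to 6.52) and Nedd1 (9.21, others 6.25 to 6.64). The spots of Pgc2, Abhd4 and Nedd1 lie close together in the same block, at rows 8 to 11 and columns 24 to 25. A local patch on that array was not tested. Male WSP air replicate 2-2 stood apart for Abhd4 (5.78, others 5.93 to 5.95) and Dio2 (7.47, others 7.90 to 7.97), and male WSP air replicate 1-1 for the Golgi SNARE GS15 (7.96, others 7.71 to 7.73). Female WSP air replicate 1-1 stood apart for Abhd4 (7.87, others 6.31 to 6.41), and female WSR air replicate 1-2 for Dock5 (6.54, others 6.98 to 7.05). Female WSP air replicate 2-1 stood apart for 2310011J03Rik (6.76, others 6.99 to 7.03) and Slc9a7 (6.52, others 6.75 to 6.79).

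The array left out by the submitters, female WSR ethanol replicate 2-1, had 31.6% of features above background, and its Spearman rho with the other arrays of its group lay between 0.340 and 0.391, where those among themselves lay between 0.126 and 0.347. Control spots exceeded the background on between 5.21% and 100% of their number per array (median 78.4%, against 49.3% for features).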

How the results depend on the processing

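Tests run under alternatives chosen after seeing the data were those with the common median, the centring of blocks and rows, the fits that use the range of the arrays and the fits of each sex alone. Signal over background limits what narrow-range arrays can show, as a median of 27.6% of features exceeded it there. The counts of 0 from limma in male WSP, male WSR and the sex interaction (45, 39 and 161 features at an unadjusted p under 0.05), and of 0 gene lists from camera in the averaged ethanol comparison, held under every whole-set alternative run for them, and the correlation of effects lay between -0.02 and 0.06. For the lists in the other comparisons these alternatives were not run. The authors' value table gave no value for the lists, as too few of their genes had a value on every array. Fitting only the groups compared uses all arrays for the averaged comparison, the interactions and the lists, so it gave no other value there. Unless stated, the cause of a change was not tested.

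For ethanol in female WSR, the count of 5 became 9 without background correction, 739 with median scaling (424 higher), 959 with cyclic loess (578 higher), 0 with the authors' value table, which allowed 616 features to be tested, 21 without the dimmest features at the stricter limit, and 25 with the excluded array. It was 3 with a common median, 9 with blocks centred, 11 with the range as a block, and 0 with the spread of the compared groups, the replicate block, array weights, rows centred with array weights, narrow-range arrays alone and females alone. In female WSP the count of 0 became 6 with array weights and 5 with wide-range arrays. With cyclic loess the averaged count of 0 became 1 and that of the line interaction 10.

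For the sexes in air, the count of 527 became 153 with median scaling (66 shared, with the median of all features shifted by -0.11), 57 with cyclic loess (52 shared) and 0 with the range as a block (signed median 0.28 in place of 0.57, median SE 0.18 in place of 0.14), and was 358 to 712 under the others. Of the calls 23.1% were higher in females, against 61.4% with cyclic loess. For WSP against WSR in air, the count of 9 became 17 with median scaling, 17 with cyclic loess, 48 with the authors' table (981 features tested), 1 with the compared groups alone, 1 with selection replicate as a block, 44 with the replicate block, 4 with a trended robust prior and 152 with array weights. It was 23 with blocks centred, 21 with rows centred, 72 with rows centred and array weights, and 0 with the range as a block.

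Leaving out 1 array at a time gave 7 to 191 calls in female WSR (191 without ethanol replicate 1-1, of which 154 were higher, 124 without ethanol 2-2, of which 113 were higher, 66 without ethanol 1-2, of which 42 were higher, 56 without air 1-2, 23 without air 1-1 and 16 without air 2-2). The sex interaction gave 0 to 3 (3 without female WSR air 1-1) and the line interaction 0 to 1 (1 without female WSR air 2-2). The sexes in air gave 303 to 657 (303 without female WSP air 2-1 and 338 without female WSP air 1-1). Over all alternatives the call was lost for MAZR in 22 of 31, U2af1l4 in 14 of 33, Nedd1 in 11 of 31, Pgc2 in 9 of 32 and Abhd4 in 7 of 30. WSP against WSR gave 0 to 27, and each of the 16 arrays moved its count. It was 27 without female WSR air 2-2, 25 without female WSR air 1-2, 16 without female WSP air 2-1 and 14 without female WSR air 1-1, and 4 without female WSP air 1-1, male WSP air 1-2 or male WSR air 1-1. It was 3 without male WSP air 1-1, 1 without male WSR air 2-2, and 0 without female WSP air 1-2 or 2-2, male WSP air 2-1 or 2-2, or male WSR air 1-2 or 2-1. Without female WSR air 2-1 it was 2, and 2310011J03Rik (adjusted p = 0.0559) and Slc9a7 (0.0750) did not pass, their calls being lost in 19 and 18 of 32 alternatives.

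For the 172 named values, 2689 results under whole-set alternatives comprised 2540 on the same side of the threshold (37 of them with the opposite sign and uncalled), 44 that came to pass and others that ceased to. With single arrays left out, 3774 of 3862 stayed on the same side (26 with the opposite sign and uncalled), 23 came to pass and 65 ceased to.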

Other observations

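The tests here, except the one with array weights, were chosen after the data had been seen. Within the wide-range WSP arrays (4 female and 8 male, air and ethanol, treatment as a covariate), 33 features were higher and 51 lower in females. Of 26 named ones, 5 were higher, with 1600014C10Rik at 0.69 ± 0.16 (log2, adjusted p = 0.0202), macrophage expressed gene 1, a pore-forming protein of macrophages, at 0.62 ± 0.14, the steroid hydroxylase cytochrome P450 2a4 at 0.54 ± 0.11, the synaptic scaffold Homer3 at 0.46 and Nedd1 at 0.44. Among the 21 lower ones, apolipoprotein A-IV, a lipid transport protein, had the smallest adjusted p (-0.72 ± 0.13, adjusted p = 0.00622). Also lower were delta-like 3 (-0.75 ± 0.15), SH3 domain protein 3 (-0.67), G protein beta 2 (-0.63 ± 0.13), Mbd2 (-0.61), Dtx4 (-0.60), RhoC (-0.51 ± 0.12) and G protein alpha 11 (-0.44 ± 0.10). By treatment, 1600014C10Rik stood at 0.32 in air and 1.07 in ethanol, and delta-like 3 at -0.34 in air and -1.15 in ethanol. With rows of spots centred, 136 features were called, 54 of them shared, and Nedd1, Homer3, G protein alpha 11 and RhoC no longer passed (adjusted p = 0.180, 0.0636, 0.0703 and 0.227).

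In female WSP with array weights, ethanol was followed by higher BCKDH E1 beta (0.93, adjusted p = 0.0198), Mx2 (0.87, adjusted p = 0.0425), Plekha5 (0.63, adjusted p = 0.0442) and leptin receptor (0.58, adjusted p = 0.0442), none of which passed without weights. With the wide-range arrays alone they stood at 0.51, 0.45, 0.22 and 0.22 and did not pass, and with rows of spots centred as well as array weights limma called 0 features (444 at an unadjusted p under 0.05, smallest adjusted p = 0.0810).

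Whether the sex difference in air itself differs between WSP and WSR was tested by interaction, where limma called 0 features and 485 had an unadjusted p under 0.05 (smallest adjusted p = 0.111). Narrow minus wide arrays of female WSP, with treatment as a covariate, differed in 106 features, 4 of them higher and the others lower, and 67 of the 106 were among the 527 called between the sexes, all in the same direction. The female WSP air arrays took part in both fits, which favours a shared direction. The effects of ethanol in the 2 selection replicates of a line correlated across features at -0.118 in male WSP, -0.110 in male WSR and -0.0475 in female WSP, each with an adjusted exact one-sided p of 0.944. Each r came from 36 arrangements, in which swapping treatment in both replicates gives the same r. This p could therefore not fall under 0.05, and the test could not have shown a response.

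The blocks of spots held between 11.1% (ethanol in male WSP) and 39.1% (ethanol in female WSR) of the variance of log2 differences over the 9 comparisons. Of 321 features in the block that holds origin of replication 3 homolog, 58 were called between the sexes, all lower in females, and of 322 in the block that holds Clstn2, 52 were called, 47 of them higher. The Y-linked Eif2s3y had a mean log2 signal of 6.67 on male arrays, 6.64 on wide-range and 6.43 on narrow-range female arrays.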
